A study of Arabidopsis thaliana with 48 samples.

How the data were processed

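Gene expression was measured with Affymetrix ATH1 arrays in RNA from pooled whole seedlings of Arabidopsis thaliana, 48 arrays in 9 groups. The deposited table holds log2 expression values, which the authors made by robust multi-array average (RMA) with the affy package, with no version given. RMA corrects background, normalises the arrays to 1 distribution by quantiles and summarises the probes of each probe set. Values ran from 1.241 to 13.132 and the median of the probe set means was 4.699. Arrays give no counts, so the number of arrays limits the precision.

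Of 22810 probe sets, 64 controls were left out and 22746 were tested. Gene names came from a reference table that pairs loci with symbols. It gave 13513 probe sets a single gene, 13355 genes in all, of which 13484 probe sets matched a current locus. Another 503 probe sets named several genes and 8730 were not in the table, so these stayed in all counts without a name. The genes changed in the lines, CCA1 and the pif4 pil5 pair, were among those without a name here, so the lines were not checked at their own genes.

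Groups were taken from the labels: genotype, minute of the day and light or dark. The group sizes were 5 or 6 arrays. Replicates came from following days, days 4, 5 and 6 after germination, and from 2 time courses hybridised in 2 array campaigns of 24 arrays each. The p-values therefore measure the spread between these pooled samples, not between single plants. The labels also give 5 array batches of 8, 16, 4, 8 and 12 arrays. The main contrasts were not fitted in each batch in turn, and batch was instead used as an additive block. A comparison of days within array batch 2 was added after the data were seen.

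Each probe set was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 48 arrays and 39 residual degrees of freedom. The median residual SD was 0.244 on the log2 scale. Contrasts of group means were tested two-sided with moderated statistics, and p was adjusted by Benjamini-Hochberg over all 22746 probe sets at a threshold of 0.05. Adjusted p below always refers to this test or, for gene lists, to the limma camera test. The contrasts averaged several groups with equal weight. An interaction contrast tested whether a difference in Col differed from that in CCA1OX. A probe set was counted as associated with growth when it passed the threshold in each of 3 contrasts of a growing with a non-growing dark group, in the direction of growth. Because these contrasts share control groups, the count was set beside 100 simulations of unchanged groups and 50 random splits of the shared controls.

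Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, on 1 probe set per gene. Of 21 lists fixed in advance, with 319 genes, 48 genes had a name on the array here. The 7 lists with at least 3 named members were tested: shade markers, Aux/IAA genes, other auxin response genes, gibberellin genes, expansins with xyloglucan endotransglucosylases, light-harvesting and Rubisco genes, and cold-regulated genes. The remaining fixed lists, among them clock genes and markers of other organs, had too few named members to test. A further 24 lists of gene families and pathways were written after the naming table was read and before any test. Adjustment ran over the 31 lists of each contrast. Members past the threshold were counted over all probe sets and, for the fixed lists, also adjusted over the list alone.

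Groups, contrasts, tests, fixed lists, the rule for naming genes and most alternatives were chosen before the data were examined. The rule names, for each main contrast, the 5 highest and 5 lowest changes among called probe sets with a single gene, and up to 3 called members of each list. The other contrasts name the 3 highest and 3 lowest. Genes outside the rule are said to be so where they appear. Added after the data were seen were 6 comparisons, a block for array campaign, covariates for RNA quality and the removal of arrays that stood apart. The RNA quality measure was the difference between 3' and 5' control probe sets for actin and GAPDH.

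The alternatives were 3 block designs, each array campaign alone, median centring, a repeated quantile normalization, removal of dim probe sets, a trended and robust variance prior, array weights, a fit of only the groups compared, and each array left out in turn. The replicate block used the number in the sample titles, 1 or 2, which names the time course in Col and CCA1OX and differs from the running replicate numbers that name arrays in this text. Residuals of these lines correlated by 0.297 within a time course and day, by 0.0781 within a time course on different days, and by -0.158 between time courses. The samples therefore pair mostly within a day of a time course, while the title number marks the time course alone, and each time course of these lines was also 1 array campaign. In pif4 pil5 the residuals did not pair with Col of the same number (-0.0205, against 0.0282 for other numbers), so the replicate block says nothing about pairing there.

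The pipeline was tested on simulated data in which 67, 67 and 66 probe sets changed by 1.5, 2 and 4-fold. At a 2-fold change it recovered 100.0% for CCA1OX against Col over all times, 89.6% for Col dark 280 min against 1240 min, 92.5% for Col dark against light, 86.6% for CCA1OX against Col at 1240 min and 92.5% for pif4 pil5 against Col. At 1.5-fold the shares were 88.1%, 44.8%, 77.6%, 50.7% and 58.2%, in that order. False calls numbered 2 to 11 among 22746 probe sets. The simulated noise was independent between arrays and between probe sets, with no campaign, batch or day in it. These shares and false calls therefore hold for such noise and not for the structure of the real arrays. A simulated list of 13 genes shifted by 1 log2 unit gave an adjusted p of 2.47e-16 and was found, while a shift of 0.5 gave 5.43e-02 and was missed.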

Results

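Seedlings were grown in short days and moved at dawn of day 4 to 3 light and dark cycles a day, each with 160 min of light and 320 min of dark. RNA of pooled seedlings was hybridised to 48 arrays. The material was the accession Col (21 arrays), a line labelled CCA1OX (21 arrays), which overexpresses a transcription factor of the circadian clock, and a double mutant labelled pif4 pil5 (6 arrays), which lacks a pair of phytochrome-interacting transcription factors. Col and CCA1OX were sampled in the light 120 min into the day (5 arrays each), in the dark at 280 min (6 each), in the light at 1080 min (5 each) and in the dark at 1240 min (5 each), and pif4 pil5 in the dark at 280 min (6 arrays). Hypocotyls were labelled growing in Col at dark 280 min and in CCA1OX at dark 280 and 1240 min. They were labelled not growing in Col at dark 1240 min, in pif4 pil5 at dark 280 min and in every light group. Array medians lay between 4.566 and 4.803 on the log2 scale. No pair of arrays was identical (0 pairs), and the lowest correlation within a group was 0.945.

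In 3 arrays of the first campaign, genes that respond to light did not follow the label. A darkness score was built from 210 probe sets higher and 354 lower in the dark in the second campaign alone. Col dark 280 replicate 3 scored -0.65 and CCA1OX dark 280 replicate 2 scored -0.55, where the other first-campaign dark arrays scored 0.60 to 1.63. Col light 1080 replicate 3 scored 1.26, where the other light arrays of that campaign scored -0.88 to 0.05. The transcription factor gene HYH, a bZIP relative of the light regulator HY5, gave the same picture. It stood at 2.58 in Col light 1080 replicate 3 against 5.35 to 6.35 in the rest of its group, and at 5.76 in CCA1OX dark 280 replicate 2 against 1.86 to 2.46. All 48 arrays were kept under their labels, and the count of each contrast chosen beforehand is also given with 45 arrays, a comparison chosen after the scores were seen.

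**Figure D1:**
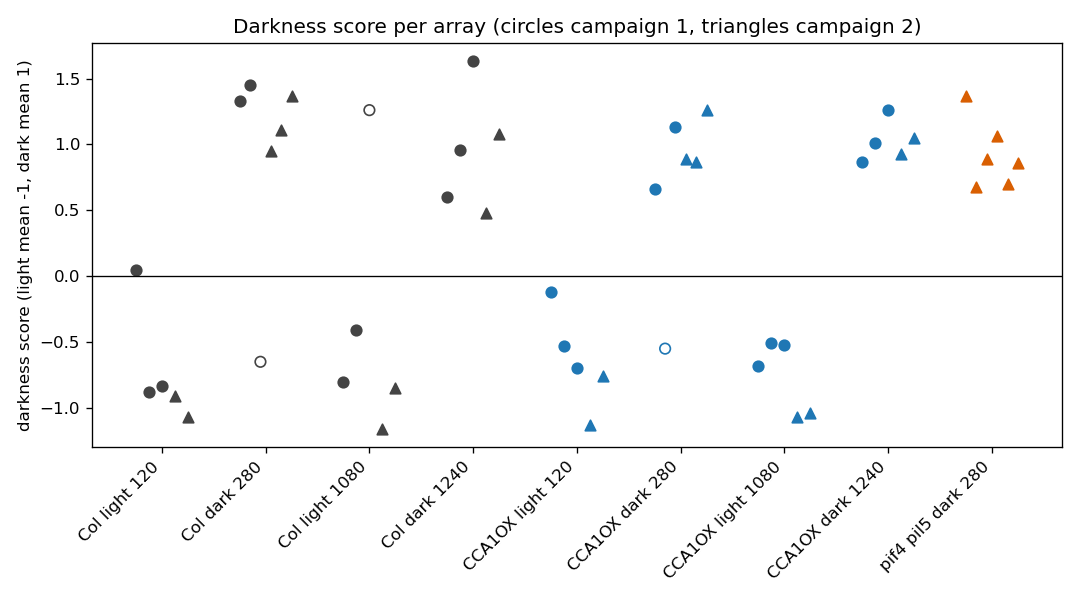
Darkness score of each array by group, scaled so that in the second campaign light arrays average -1 and dark arrays 1 (circles, first campaign; triangles, second campaign; open symbols, the 3 arrays that stood apart). Col dark 280 replicate 3 (-0.65) and CCA1OX dark 280 replicate 2 (-0.55) lie among light arrays and Col light 1080 replicate 3 (1.26) among dark arrays.

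Light and dark were compared within each line to find the genes that follow the short cycles. In Col, HYH fell by 2.00 ± 0.392 (log2 change ± SE, adjusted p = 2.12e-03) from light to dark, and the evening clock gene GI fell by 1.93 ± 0.451 (adjusted p = 9.37e-03). By the group means the fall of GI lay mostly at 1240 min, with dark means of 5.83 ± 1.72 (SD) at 280 and 3.52 ± 0.35 at 1240 min. Its light means were 6.73 at 120 and 6.48 at 1080 min. Arrays that stood apart enter these means, with GI at 8.24 in dark 280 and 4.05 in light 1080. The day 4 arrays of dark 280 stood at 7.09 and 6.51 and the rest at 3.85 to 5.05, so the pattern over time depends on day and on these arrays. The cysteine protease gene AT2G27420 fell most among the named genes, by 2.94 ± 0.617. Higher in the dark were the auxin-conjugating enzyme gene GH3.3 (1.44 ± 0.290, adjusted p = 2.76e-03) and AT3G15450 (1.97 ± 0.492, adjusted p = 1.52e-02). The rise of GH3.3 lay mostly at 280 min, with 8.04 at dark 280 and 5.92 at dark 1240 min. Its light means were 5.61 at 120 and 5.47 at 1080 min. HYH averaged 5.46 ± 0.90 and 5.12 ± 1.47 (SD, n = 5 each) in the light groups of Col at 120 and 1080 min, and 3.12 ± 0.92 (n = 6) and 3.45 ± 0.79 (n = 5) in the dark groups at 280 and 1240 min. The light signalling genes HYH, AT3G52740 and AT3G44450 all fell in the dark, with a median of -1.43 (camera adjusted p = 5.76e-07), as did 2 of 7 flavonoid pathway genes, CHIL (-1.42) and UGT78D2 (-1.30), whose list call did not hold (adjusted p = 0.291 with an estimated correlation). CHIL lost its call without Col light 1080 replicate 1 or 4 or Col dark 1240 replicate 3, UGT78D2 without any of 15 single arrays, and AT3G15450 without Col dark 1240 replicate 3. In all, 738 probe sets differed in Col, 301 higher and 437 lower in the dark. Of these 156 changed at least 2-fold.

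With limma the Col count was 0 in the first campaign alone (1448 at an unadjusted p under the threshold), which holds the arrays standing apart, and 676 in the second, where HYH fell by 2.62. It was 2045 with 45 arrays, 1164 with array batch as a block and 1288 with time course and day as blocks. Leaving out 1 array mattered most for Col light 1080 replicate 3 (1430), Col dark 280 replicate 3 (1313) and Col light 1080 replicate 1 (471).

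In CCA1OX the auxin-induced repressor gene IAA29 rose in the dark by 3.66 ± 0.53, or 12.7-fold (adjusted p = 7.68e-06), and AT5G02540 and AT3G15450 rose by 3.22 and 3.09. AT3G28270 fell by 3.64 and AT2G27420 by 3.62. All 4 named shade markers, IAA29, HAT2, FHL and AT1G69570, rose with a median of 1.2 (camera adjusted p = 2.88e-08). Flavonoid pathway genes fell in 4 of 7 cases (median -1.21, camera adjusted p = 3.51e-04), and UDP-glycosyltransferase genes fell in 11 and rose in 2 of 47 (camera adjusted p = 2.53e-03). Starvation genes rose in 4 of 10 cases (camera adjusted p = 2.09e-03). These last 3 list calls were lost when the correlation between genes was estimated (adjusted p = 0.0930, 0.0930 and 0.109 with an estimated correlation). Probe sets called in CCA1OX numbered 2329, 1125 higher and 1204 lower in the dark, and centring the array medians moved the share that was higher from 48.3% to 37.1%. With limma the count was 0 in the first campaign (2517 at an unadjusted p under the threshold) and 1915 in the second, and 3020 with 45 arrays.

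Col and CCA1OX shared 565 light-regulated probe sets, all in the same direction (38.0 by chance). A test of the difference between the lines found 1 probe set, which had no gene name. Its dark minus light difference was lower in Col by -2.88 ± 0.50 (adjusted p = 2.18e-02), and 858 probe sets had an unadjusted p under the threshold. That call was lost without any of 7 single arrays, in either campaign alone and with RNA quality covariates. With 45 arrays the count was 8. Shade markers as a list differed (median -1.0, camera adjusted p = 3.26e-09), rising more in CCA1OX, with medians of -0.98 and -1.13 in the campaigns. For IAA29, HAT2 and AT1G69570 the lines differed mostly at dark 1240 min, with Col at 4.71, 6.88 and 3.68 and CCA1OX at 8.32, 8.10 and 6.23. At dark 280 min Col stood at 6.42, 7.71 and 5.17 and CCA1OX at 7.43, 7.85 and 5.74. This call is therefore not separate from the comparison at dark 1240 min below.

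Dark samples of Col at 280 min, labelled growing, were compared with those at 1240 min, labelled not growing, to find genes that go with the daily stop of elongation. GH3.3 was higher at 280 min by 2.12 ± 0.402, or 4.35-fold (adjusted p = 8.04e-03), with means of 8.04 ± 0.55 (SD, n = 6) and 5.92 ± 0.73 (n = 5). WES1, a related gene whose enzyme conjugates auxin to amino acids, was higher by 1.26 ± 0.234, or 2.40-fold (adjusted p = 6.66e-03). AT1G69570, a Dof-type transcription factor gene on the shade list, was higher by 1.49 ± 0.290, or 2.81-fold (adjusted p = 1.08e-02). AT1G73480, a hydrolase gene, was higher by 1.96 ± 0.276 (adjusted p = 1.13e-04). The calcium-binding protein gene AT4G27280 was higher by 1.1 ± 0.188. In these 5 genes every array lay beyond the mean of the other group, 6 of 6 and 5 of 5. GH3.3 lost its call without Col dark 1240 replicate 1 and AT1G69570 without replicate 4 of that group. In all, 21 probe sets were higher and 2 lower at 280 min, 17 of the 23 by at least 2-fold.

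By list, 2 of 4 other auxin response genes rose (2 adjusted over the list alone, median 0.80, camera adjusted p = 2.03e-06) and 1 of 4 shade markers (3 adjusted over the list alone, median 1.16, camera adjusted p = 8.72e-06). The first list held (adjusted p = 3.00e-03 with an estimated correlation) and the shade markers narrowly did not (adjusted p = 5.28e-02 with an estimated correlation). Expansin and xyloglucan endotransglucosylase genes had a median of 0.35 (0.52 and 0.19 in the campaigns) with 0 of 13 members called by limma. Their list call (camera adjusted p = 1.99e-02) was lost (adjusted p = 0.174 with an estimated correlation). The other auxin response genes and the shade markers kept their direction in each campaign, with medians of 0.98 and 0.66 for the other auxin response genes and 1.07 and 1.25 for the shade markers. The count of 23 was 9 in the first and 3 in the second campaign, 54 with 45 arrays and 0 when limma was fitted to only the groups compared (803 at an unadjusted p under the threshold, against 1200 over all groups). Without Col dark 280 replicate 1 or 2 it was 15, without Col dark 1240 replicate 1 it was 12 and without replicate 4 of that group 11.

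CCA1OX, labelled growing at both times, was compared over the same times. It overexpresses a clock transcription factor, so it is no control for the time of day alone. A changed clock and constant growth would both leave no difference here. GH3.3 averaged 6.78 ± 1.21 (SD, n = 6) at 280 min and 6.96 ± 0.56 (n = 5) at 1240 min, and IAA29 7.43 ± 1.55 (n = 6) and 8.32 ± 0.19 (n = 5). No probe set passed with limma (0, with 303 at an unadjusted p under the threshold), and with 45 arrays the count was also 0. Among lists, shade markers had a median of -0.37 at 280 against 1240 min (camera adjusted p = 1.59e-02), and without CCA1OX dark 280 replicate 2, which stood apart, it was -0.18 and missed the threshold. Chloroplast-encoded photosystem genes had a median of -0.27 (camera adjusted p = 6.58e-04). Neither call, nor any other list call of this comparison, held with an estimated correlation.

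The difference between the lines was tested itself. Because CCA1OX overexpresses a clock factor, this test does not separate growth from the time of day. For single probe sets limma again called 0, with 381 at an unadjusted p under the threshold, and 2 with 45 arrays. Shade markers differed by a median of 1.52 (camera adjusted p = 2.33e-09), other auxin response genes by 0.99 (camera adjusted p = 3.51e-08) and Aux/IAA genes by 0.20 (camera adjusted p = 1.21e-02). Adjusted over the list alone, 3 of 4 shade markers and 2 of 4 other auxin response genes passed. The medians in the first and second campaigns were 1.66 and 1.41 for the shade markers and 1.36 and 0.66 for the other auxin response genes.

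**Figure D2:**
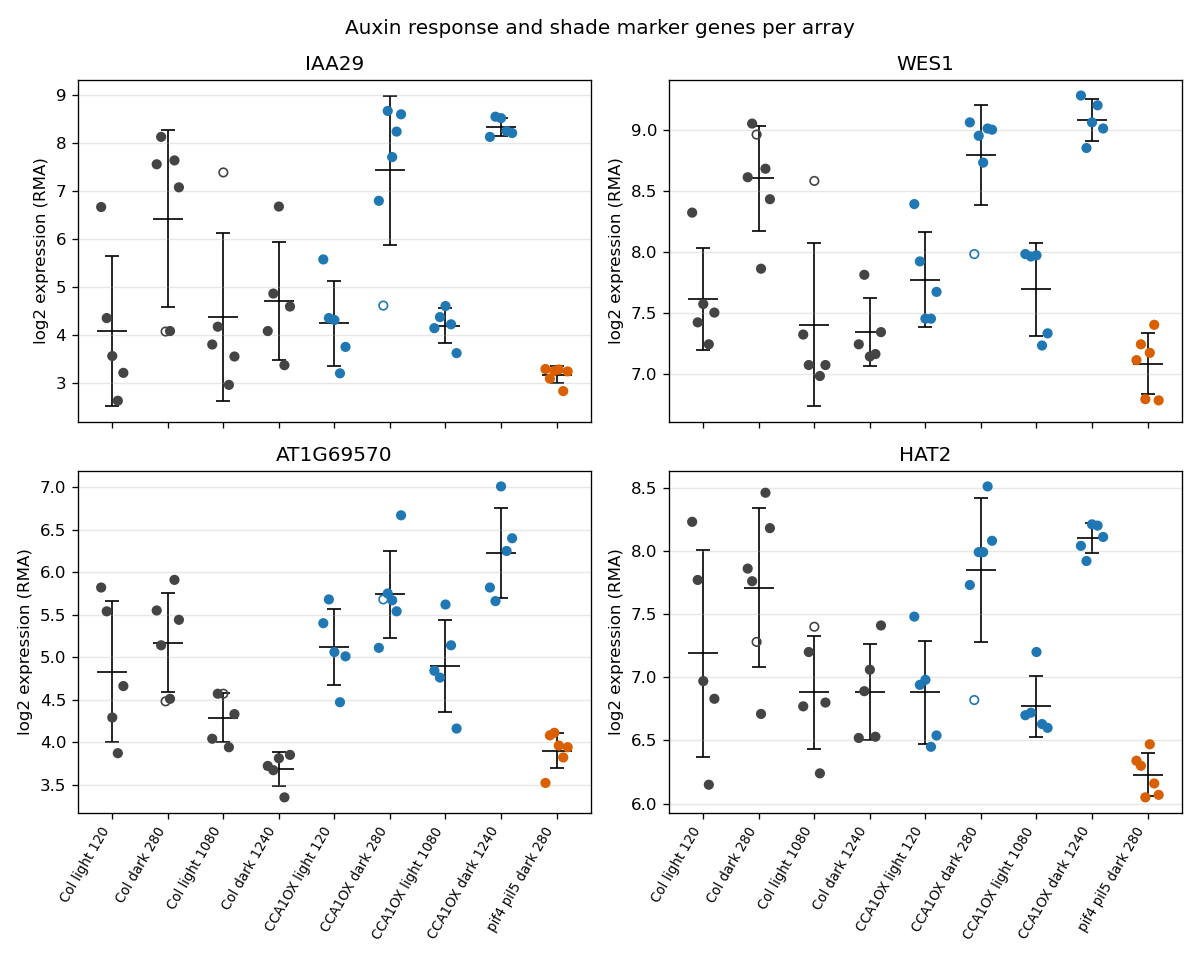
Log2 expression (RMA) of IAA29, WES1, AT1G69570 and HAT2 per array in the 9 groups (Col grey, CCA1OX blue, pif4 pil5 orange; long bars, mean; whiskers, SD; open circles, the 3 arrays that stood apart). In the dark IAA29 averages 6.42 in Col at 280 min, 4.71 in Col at 1240 min, 8.32 in CCA1OX at 1240 min and 3.2 in pif4 pil5 at 280 min.

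At dark 1240 min CCA1OX was labelled growing and Col not growing, so the lines were compared at this time. IAA29 was higher in CCA1OX by 3.61 ± 0.760, or 12.2-fold (adjusted p = 7.20e-03), with means of 8.32 ± 0.19 and 4.71 ± 1.23 (SD, n = 5 each). AT1G69570 was higher by 2.55 ± 0.303, or 5.84-fold (adjusted p = 1.06e-06), and WES1 by 1.74 ± 0.245, or 3.34-fold (adjusted p = 1.71e-05). The shade-responsive homeodomain gene HAT2 was higher by 1.21 ± 0.290 (adjusted p = 2.69e-02). GI was higher by 2.85 ± 0.652, or 7.20-fold (adjusted p = 1.64e-02), at 6.37 ± 0.31 in CCA1OX and 3.52 ± 0.35 in Col. AT4G35720 (2.72 ± 0.410) and AT5G50335 (2.35) were also higher. AT3G25150, which encodes a protein with a nuclear transport factor 2 domain, was lower by -2.05 ± 0.179 (adjusted p = 1.72e-10). All of these had 5 of 5 arrays of each line beyond the mean of the other. IAA29 and WES1 missed the threshold in the first campaign alone, at 3.18 and 1.66, and kept it in the second, at 4.24 and 1.86. The call for GI was lost without CCA1OX dark 1240 replicate 3 or 5 or Col dark 1240 replicate 4 or 5, and that for HAT2 without any of 7 single arrays.

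Shade markers rose in 4 of 4 cases (median 1.88, camera adjusted p = 1.37e-15). Expansin and xyloglucan endotransglucosylase genes rose in 2 of 13, EXLA2 (0.80) and EXLA3 (0.57) (3 adjusted over the list alone, median 0.57, camera adjusted p = 1.07e-07). EXLA2 and EXLA3 kept their direction but missed the threshold after median centring and without any of 8 and 4 single arrays. Other auxin response genes rose in 1 of 4 cases (2 adjusted over the list alone, camera adjusted p = 1.74e-04). Cold-regulated genes had a median of 1.66 (camera adjusted p = 1.35e-02), with 0 of 3 called by limma over all probe sets and 1 adjusted over the list alone, and this list call was lost (adjusted p = 0.101 with an estimated correlation). In all 132 probe sets were higher and 9 lower in CCA1OX, 88 by at least 2-fold, from 1588 at an unadjusted p under the threshold. The count of 141 was 16 in the first and 106 in the second campaign, 210 with 45 arrays and 261 with array batch as a block. The medians of the shade markers were 1.83 and 2.01 in the campaigns, and those of the expansin and xyloglucan endotransglucosylase genes 0.50 and 0.73.

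The double mutant pif4 pil5, labelled not growing, was compared with Col at dark 280 min, labelled growing. IAA29 was lower in the mutant by -3.26 ± 0.694, or 9.56-fold (adjusted p = 1.49e-02), with means of 3.2 ± 0.18 and 6.42 ± 1.85 (SD, n = 6 each). HAT2 fell by 1.48 ± 0.265, or 2.78-fold (adjusted p = 2.85e-03), and WES1 by 1.52 ± 0.224, or 2.87-fold (adjusted p = 1.57e-04). GH3.3 fell by 1.63 ± 0.383 (adjusted p = 2.98e-02) and AT1G69570 by 1.27 ± 0.276 (adjusted p = 1.86e-02). PUB43, a U-box ubiquitin ligase gene, fell by 1.11 ± 0.115 (adjusted p = 3.38e-08). The strongest call was a probe set without a gene name, lower by -4.29 ± 0.31 (adjusted p = 5.89e-13). Whether it is one of the mutated genes, which have no name here, was not checked. Among the genes higher in the mutant was AT5G50450 (0.92), a call lost without pif4 pil5 replicate 1. In these 6 genes that fell, 6 of 6 arrays of each group lay beyond the mean of the other. IAA29 lost its call without Col dark 280 replicate 1 or 2, AT1G69570 without replicate 1 or 5 of that group or pif4 pil5 replicate 1, and GH3.3 without any of 6 single arrays, while WES1, HAT2 and PUB43 kept theirs in every alternative run. IAA29 and AT1G69570 also missed the threshold when only the groups compared were fitted, and AT1G69570 in the second campaign alone.

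Shade markers fell in 3 of 4 cases (4 adjusted over the list alone, median -1.37, camera adjusted p = 1.19e-08), other auxin response genes in 2 of 4 (3 adjusted over the list alone, median -1.01, camera adjusted p = 6.51e-07) and Aux/IAA genes in 1 of 7 (camera adjusted p = 6.23e-03). The Aux/IAA gene that fell was IAA29, which is also on the list of shade markers. Of 9 U-box genes 1 fell, PUB43 (camera adjusted p = 1.29e-04). Chloroplast-encoded cytochrome b6f, ATP synthase, NDH and rbcL genes had a median of -0.40 (-0.19 in the second campaign alone) with 0 called by limma (camera adjusted p = 9.36e-06), and this call was lost (adjusted p = 0.347 with an estimated correlation). In all 46 probe sets were higher and 92 lower in the mutant, 37 by at least 2-fold, from 3274 at an unadjusted p under the threshold.

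All pif4 pil5 arrays came from array batch 5 of the second campaign, which held only replicate 6 of this Col group and 5 arrays of other Col and CCA1OX groups. In the second campaign alone 43 probe sets were called, 32 of them among the 138, with shade markers at -1.47, and with array batch as a block 152, 78 of them among the 138, with shade markers at -1.60. With the title number and day as blocks the count was 640, 306 higher and 334 lower, so the excess of lower calls was not kept there. In pif4 pil5 that number did not pair the arrays with Col. The excess was kept without Col dark 280 replicate 1 (9 higher and 34 lower) and was small without replicate 4 of that group (296 and 337). The count was 184 with 45 arrays, 21 when only the groups compared were fitted, 43 and 59 without Col dark 280 replicate 1 or 2, 633 without replicate 4 of that group, and 70 and 76 without pif4 pil5 replicate 1 or 5. The actin 3' minus 5' difference, a measure of RNA quality, was 1.2 ± 0.141 in pif4 pil5 and 1.03 ± 0.189 in Col (SD, n = 6 each).

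Across the 5 dark groups, the 3 labelled growing were compared with the 2 labelled not growing. IAA29 was higher with growth by 3.45 ± 0.467, or 10.9-fold (adjusted p = 1.74e-06), WES1 by 1.61 ± 0.150 (adjusted p = 5.63e-10), AT1G69570 by 1.92 ± 0.186 (adjusted p = 1.48e-09), HAT2 by 1.33 ± 0.178 (adjusted p = 1.51e-06) and GH3.3 by 1.09 ± 0.258. AT4G35720 was higher by 2.42 ± 0.252, AT5G02540 by 2.26 and GI by 1.97 ± 0.401 (adjusted p = 1.46e-03). The thionin gene AT1G66100 fell by 2.26 and AT1G65490 by 1.93. Expansin and xyloglucan endotransglucosylase genes rose in 4 of 13 cases (6 adjusted over the list alone, median 0.40, camera adjusted p = 4.00e-07), among them EXPB1 (0.90) and EXLA2 (0.79). Shade markers rose in 4 of 4 (median 1.62, camera adjusted p = 1.26e-14), other auxin response genes in 2 of 4 (3 adjusted over the list alone, camera adjusted p = 3.55e-06), Aux/IAA genes in 2 of 7 (3 adjusted over the list alone, camera adjusted p = 2.35e-03), cold-regulated genes in 2 of 3 (3 adjusted over the list alone, median 1.27, camera adjusted p = 2.26e-03) and U-box genes in 3 of 9 (camera adjusted p = 7.67e-05). The 1128 called probe sets were 684 higher and 444 lower with growth, an excess that shrank to 617 and 564 after median centring and was gone with time course and day as blocks (1291 and 1307). The count was 571 in the second campaign, 1223 with 45 arrays, 1889 with time course as a replicate block and 1823 without Col dark 280 replicate 4. The CCA1OX line supplies 2 of the 3 growing groups, so line and growth overlap in this comparison.

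Probe sets called in each of the 3 contrasts of growing with non-growing dark groups numbered 9, all higher with growth. Only 4 had a gene name, AT1G69570, WES1, AT4G27280 and AT4G25280. An unnamed one changed by 1.94 in Col over time, 2.30 between the lines at 1240 min and -4.29 in pif4 pil5. The mutated genes have no name here, so a fall set by the mutation itself could not be told apart for it. AT4G25280, a nucleotide-binding protein gene, changed by 0.66 in Col over time, 0.64 between the lines at 1240 min and -0.77 in pif4 pil5, and lost its first call without any of 5 single arrays. AT4G27280 fell by 0.81 in pif4 pil5, a call lost without Col dark 280 replicate 1 or pif4 pil5 replicate 6. AT1G69570 and WES1 missed the threshold between dark and light in Col (-0.14, adjusted p = 0.915, and 0.46, adjusted p = 0.140), a contrast in which the dark mean joins the growing and the non-growing group. Simulated unchanged groups that share controls in the same way gave at most 0 in 100 simulations. They held no real change in any contrast and mixed arrays across days, campaigns and batches, so a 0 there decides little. Splitting the shared controls gave a median of 0 and at most 2 in 50 splits. The contrasts of Col over time and of the lines at 1240 min shared 17 probe sets with the same direction, where independent lists would share 0.1. The simulated unchanged groups shared a median of 0 and up to 264, so shared controls alone can give 17. With the pif4 pil5 contrast these 2 contrasts shared 10 and 36, all opposite in sign, against 0.1 and 0.6 for independent lists. The simulations gave at most 0, with the same limit as above. With split controls, which keep real changes but make the groups smaller, the 3 overlaps had medians of 3.5 (0 to 12), 0 (0 to 2) and 7 (1 to 43). Over all probe sets the log2 changes of these pairs correlated by 0.43, -0.28 and -0.40 (simulated medians 0.56, -0.46 and -0.02), with covariances of 0.0255, -0.0162 and -0.0283 (simulated medians 0.0209, -0.0158 and -0.0009). For the first 2 pairs the agreement over all probe sets therefore did not exceed what shared controls give. With limma the count of 9 was 0 in the second campaign, where 3, 106 and 43 probe sets passed in the single contrasts, and 25 with 45 arrays. It was 5 without Col dark 280 replicate 1 or Col dark 1240 replicate 1, 16 without Col dark 280 replicate 3 and 3 without Col dark 1240 replicate 4.

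CCA1OX was compared with Col averaged over the 4 times of day to find differences of the line at any time. The cold-regulated genes COR15A and COR15B, which encode chloroplast proteins that protect membranes during freezing, were higher in CCA1OX by 2.41 ± 0.428 (5.32-fold, adjusted p = 1.60e-04) and 2.35 ± 0.339 (5.09-fold, adjusted p = 6.82e-06). COR15B averaged 6.75 to 8.20 in the CCA1OX groups and 4.54 to 5.59 in the Col groups. Single Col arrays reached CCA1OX levels. The highest were Col dark 280 replicate 3, which stood apart (8.43), Col light 1080 replicate 5 (7.89) and Col dark 1240 replicate 3 (7.68). AT3G25150 fell by 2.37 ± 0.087, or 5.18-fold (adjusted p = 4.73e-24), with Col groups at 7.00 to 7.25 and CCA1OX groups at 4.44 to 5.15. GI was higher by 1.46 ± 0.319 (adjusted p = 2.01e-03), and the sugar transporter genes SWEET3 and SWEET14 moved apart, by 1.36 ± 0.206 (adjusted p = 1.47e-05) and -1.33 ± 0.189 (adjusted p = 5.10e-06). AT1G66100 fell by 2.50 ± 0.339 and the pectin methylesterase gene ATPMEPCRD rose by 1.81 ± 0.300. Cold-regulated genes rose in 2 of 3 cases (median 2.35, camera adjusted p = 7.10e-04), with medians of 1.87 and 2.82 in the campaigns, but the call did not hold (adjusted p = 5.67e-02 with an estimated correlation). Chloroplast-encoded ribosomal protein and RNA polymerase genes fell in 5 of 19 (median -0.36, camera adjusted p = 1.43e-04), among them rps16 (-1.09 ± 0.290, adjusted p = 1.07e-02), and this list call was lost as well (adjusted p = 0.401 with an estimated correlation). Gibberellin genes passed the list test in no contrast, with adjusted p from 0.0954 to 0.971, and GID1A alone rose here (0.24). Light-harvesting genes passed in none either, with adjusted p from 0.348 to 0.911. In all 2473 probe sets differed, 1329 higher and 1144 lower in CCA1OX, with a median size of 0.34 and only 82 at 2-fold or more. The count was 209 in the first and 3438 in the second campaign, 2966 with 45 arrays and 4056 with array batch as a block.

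**Figure D3:**
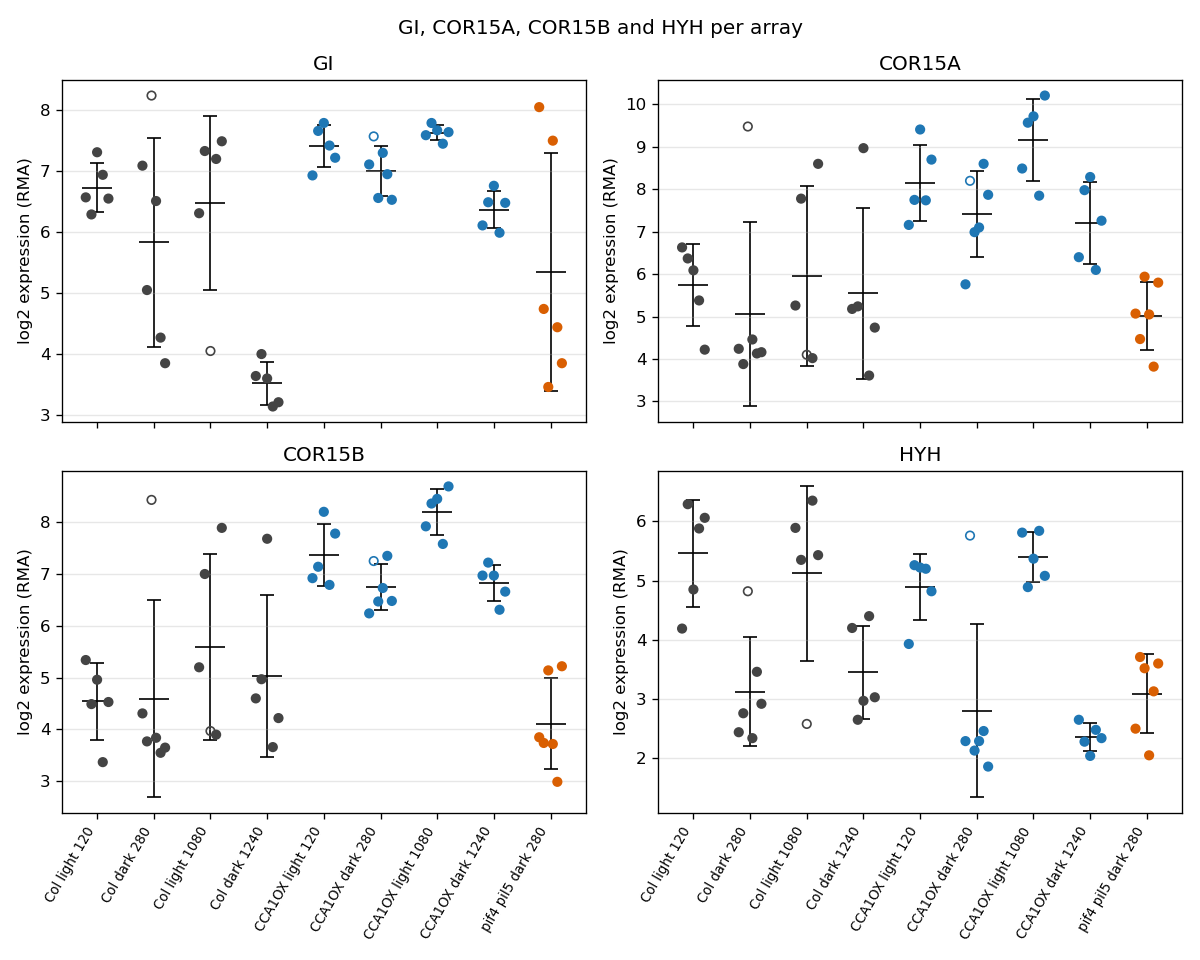
Log2 expression (RMA) of GI, COR15A, COR15B and HYH per array in the 9 groups (Col grey, CCA1OX blue, pif4 pil5 orange; long bars, mean; whiskers, SD; open circles, the 3 arrays that stood apart). GI averages 3.52 in Col and 6.37 in CCA1OX at dark 1240 min, and COR15A reaches 9.48 in the open circle of Col dark 280, where the rest of the group lies between 3.88 and 4.46.

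Some of the list calls above also held when the correlation between genes was estimated. Shade markers and other auxin response genes held in the difference between the lines over time, at 1240 min, in pif4 pil5 and with growth, and expansin and xyloglucan endotransglucosylase genes held at 1240 min and with growth (the largest of these adjusted p = 1.58e-02 with an estimated correlation). Aux/IAA genes held in the same 4 contrasts, cold-regulated genes with growth, and U-box genes in pif4 pil5 and with growth. IAA29 is on both the shade and the Aux/IAA list, so the calls of these lists are not independent. In pif4 pil5 the only members that fell past the threshold were IAA29 in the Aux/IAA list and PUB43 in the U-box list. Light signalling genes held in both lines from light to dark, shade markers held in CCA1OX and in the difference of the lines in their response to light. In IAA29, HAT2 and AT1G69570 that difference lay mostly at dark 1240 min. None of the list calls of CCA1OX against Col over all times held with an estimated correlation.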

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

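The tests of the 3 arrays that stood apart, the test of array batch in pif4 pil5, the covariates for RNA quality and the light comparisons of CCA1OX with Col were chosen only after the results they bear on were seen. The values of 8 genes were examined in each group, 72 sets in all, and in 8 of them a single array lay far from the rest, where chance gives about 1 in 20. These 8 values come from 5 arrays, and 6 of them from the 3 arrays that stood apart. In Col light 1080 replicate 3, IAA29 stood at 7.38 (others 2.96 to 4.17), WES1 at 8.58 (6.98 to 7.32) and HYH at 2.58 (5.35 to 6.35). In CCA1OX dark 280 replicate 2, WES1 stood at 7.98 (8.73 to 9.06) and HYH at 5.76 (1.86 to 2.46). In Col dark 280 replicate 3, COR15A stood at 9.48 (3.88 to 4.46).

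These 3 arrays of the first campaign carried light-regulated genes that go against their light label. A poor array or degraded RNA is argued against, since their correlation over all probe sets with the group they match best was 0.977 or more. That lay inside the 0.967 to 0.990 of the other 21 arrays with their own groups, although the best group was taken for these 3 alone. With their own groups they stood at 0.962, 0.966 and 0.977. For a shift of the whole campaign, 21 of 24 first-campaign arrays correlated above 0 with their own group. This cannot decide, since centring within the campaign removes such a shift and the 3 arrays were chosen by this correlation. In the darkness score, not centred by campaign, its other arrays lay at 0.60 to 1.63 in the dark and -0.88 to 0.05 in the light. What stays open is that a label may be wrong or samples may have been exchanged, since each of the 3 correlated negatively with its own group (-0.58 at most) over the light-regulated probe sets and best with a group of the other light condition, Col light 1080 (0.62), Col dark 280 (0.74) and CCA1OX light 1080 (0.80). An exchange of the Col pair with each other is not settled, since over all probe sets Col light 1080 replicate 3 matched Col dark 1240 best (0.978), and WES1 in Col dark 280 replicate 3 was 8.96, inside the 7.86 to 9.05 of the rest of that group and above the 6.98 to 7.32 of the other Col light 1080 arrays, while CCA1OX dark 280 replicate 2 has no partner out of place. The first rule tried, a score on the other side of 0, also took Col light 120 replicate 1 (score 0.05, correlation with its own group 0.37), and the rule was changed to a correlation below 0 after that outcome was seen.

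The other values far from their group were HAT2 at 7.20 in CCA1OX light 1080 replicate 3 (others 6.60 to 6.72) and GH3.3 at 5.89 in CCA1OX light 1080 replicate 5 (others 4.77 to 5.07). A probe set without a gene name differed between the lines in its response to light by -2.88 ± 0.50 (adjusted p = 2.18e-02), with Col means of 7.28 and 6.39 in the light and 4.67 and 3.79 in the dark, and CCA1OX means of 9.29 to 9.90. It was lower in the dark in 10 of 11 Col arrays and higher in 8 of 11 CCA1OX arrays, against the light mean of each line. This probe set also had the largest rise in CCA1OX over Col, 17.3-fold over all times and 69.1-fold at dark 1240 min. The gene overexpressed in the line has no name here, so whether this probe set belongs to it was not checked. Lists that differed between the lines in the dark over time were shade markers (median 1.52), Aux/IAA genes (0.20), other auxin response genes (0.99) and the added list of Aux/IAA, GH3 and other auxin response genes (0.42, camera adjusted p = 1.39e-10). Shade markers differed in the response to light by -1.0, in IAA29, HAT2 and AT1G69570 mostly at dark 1240 min.

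In pif4 pil5, 5 auxin response and shade marker genes, GH3.3, HAT2, IAA29, WES1 and AT1G69570, were lower than in Col at dark 280 min, each in 6 of 6 arrays, with a median of -1.52. RNA quality as the whole cause is argued against, since the median stayed at -1.48 (median SE 0.28) with 3' to 5' differences as covariates, where a bound of -0.76 had been set. Array campaign as the whole cause is argued against too, since it was -1.55 (median SE 0.30) against Col of the second campaign alone. An additive effect of array batch as the whole cause is argued against as well, since the median was -1.72 (median SE 0.31) with batch as a block, estimated from the 6 arrays of Col and CCA1OX in batch 5, which holds all 6 mutant arrays but only 1 Col array of this group. The absence of growth and the loss of the transcription factors themselves both remain open, untested explanations.

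Of the 1128 probe sets called between growing and non-growing dark groups, 85.4% differed in the same direction between CCA1OX and Col in the light, where neither was labelled growing, against 61.3% of all probe sets. The contrast may therefore carry a difference of the CCA1OX line that does not need growth, and 198 of the 1128 passed the threshold in the light in the same direction. For 7 called auxin response and shade marker genes a line difference that is present in the light is argued against. Their median was 1.33 with growth and -0.01 in the light (median SE 0.21, bound 0.66). A line difference confined to the dark stays open for them, since CCA1OX was labelled growing in each of its dark groups. For the cold-regulated genes COR15B and COR47 a difference of the line cannot be told apart from growth. Their median in the light was 1.33 against 1.02 with growth, from only 2 genes that move apart in the light (2.72, adjusted p = 9.77e-04, with 10 of 10 CCA1OX arrays above the Col mean and 9 of 10 Col arrays below the CCA1OX mean, and -0.07).

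Regrouping the same arrays at random, 100 splits for each comparison, showed which counts chance can give. The real grouping is 1 of the 100 and is included in each number of splits as large. Against all 100 splits, chance can be excluded for CCA1OX against Col over all times (2473 probe sets, 1 split as large, highest other 1492), CCA1OX dark against light (2329, 1 split, highest other 365), CCA1OX against Col at dark 1240 min (141, 1 split, highest other 14) and CCA1OX against Col in the light (680, 1 split, highest other 51). Of their splits 6, 23, 47 and 18, in that order, kept the campaigns as balanced as the real grouping. The highest counts of these were 0, 266, 14 and 51, all below the real counts. For the lines over all times and in the light, 6 and 18 balanced splits are too few to exclude chance by themselves. The splits were drawn without regard to day. From the splits alone, chance is not excluded for Col dark against light (738, 4 splits, highest other 1842) and pif4 pil5 against Col (138, 4 splits, highest other 622). Both met the bound set beforehand, fewer than 5 of 100 splits as large. For Col, 565 of the 738 were also called in CCA1OX, on other arrays, all in the same direction (38.0 by chance). This argues against chance for these probe sets, although samples of the lines paired within days. Among the balanced splits, 26 for Col and 8 for pif4 pil5, the highest counts were 808 and 622, so these also reached the real counts. For growing against not growing (1128, 1 split as large, highest other 7) and the growth-associated probe sets (9, 1 split, highest other 0), 0 of the splits were balanced in this way. These real counts were the largest, but only against splits with another campaign balance, so chance is not decided for them. The growth-associated probe sets also had to pass the contrast of Col over time in the dark, for which chance is not excluded below. The pif4 pil5 share is borderline, because an earlier draw that counted mirror images separately gave 5 of 100, with a highest other of 458. In 1 of the splits as large, with 343 probe sets, all 4 arrays of day 4 lay on one side and all 4 of day 6 on the other, so day is a structure of these samples.

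Chance cannot be excluded for Col dark 280 against 1240 min (23 probe sets, 6 splits as large, highest other 733). A split exactly by array campaign gave 613, so the campaigns structure these samples, and within them the count was 9 and 3. Of the other splits, 43 kept the campaigns as balanced as the real grouping, and the highest of these gave 1 probe set against 23. Nor can it be excluded for the difference of the lines in their response to light (1, 7 splits, highest other 49) or Col light 1080 against 120 min (15, 9 splits, highest other 729), where the balanced splits, 5 and 44, gave at most 1 and 227. Where limma called 0 probe sets the splits decide nothing, since all 100 are then as large by necessity: CCA1OX dark 280 against 1240 min (highest other 13), the difference between the lines in the dark over time (45), CCA1OX light 1080 against 120 min (9) and the difference between the lines in the light over time (115).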

How the results depend on the processing

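The removal of 3 or 4 arrays, the campaign block, the RNA quality covariates and the light and day comparisons were chosen only after the data were seen. No call of a single named gene reversed under any alternative run. Of 159 such calls, 65 missed the threshold in the second campaign alone, 38 when only the groups compared were fitted, 9 with array batch as a block, 8 with RNA quality covariates and 0 with the replicate block, and 93 of 105 missed it in the first campaign alone. Of 85 list calls, 53 missed it with an estimated correlation and 19 with the batch block. A pair of lists reversed in the second campaign alone, ATG8 genes in Col dark 280 against 1240 min (to 0.02) and UDP-glycosyltransferase genes in CCA1OX dark 280 against 1240 min (to 0.00). The cause of a change was not tested except where fewer arrays or probe sets were fitted.

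Counts of probe sets that moved by over 1.5 times follow, by alternative. In the first campaign alone they were 209 for CCA1OX against Col over all times, 9 for Col dark 280 against 1240 min, 0 for dark against light in Col, in CCA1OX and for their difference (1448, 2517 and 464 with limma at an unadjusted p under the threshold), 16 for CCA1OX against Col at dark 1240 min, 38 for the lines in the light and 0 for Col light 1080 against 120 min (950 unadjusted). Contrasts with pif4 pil5 have no value there, since that campaign holds none of its arrays. In the second campaign alone they were 3 for Col dark 280 against 1240 min, 1 for the difference over time, 9 for the difference in the response to light, 43 for pif4 pil5, 571 for growing, 0 for Col light 1080 against 120 min (630 unadjusted) and 0 for the growth-associated probe sets.

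With the title number as a replicate block, which marks the time course of Col and CCA1OX samples, they were 357 for pif4 pil5, 1889 for growing and 1193 for the lines in the light. With day added to that block they were 4025 for the lines over all times, 58 for Col dark 280 against 1240 min, 1 for the difference over time, 1288 for Col dark against light, 4 for the difference in the response to light, 272 for the lines at dark 1240 min, 640 for pif4 pil5, 2598 for growing, 1870 for the lines in the light, 31 for Col light over time and 15 growth-associated. With array batch as a block they were 4056 for the lines over all times, 4 for each of the 2 differences, 1164 for Col dark against light, 261 for the lines at dark 1240 min, 1830 in the light and 23 for Col light over time. A campaign block gave 1358 for the lines in the light.

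Array weights gave 4424 for the lines over all times, 53 for Col dark 280 against 1240 min, 21 for the difference over time, 1670 and 3864 for dark against light in Col and CCA1OX, 10 for their difference, 615 for the lines at dark 1240 min, 553 for pif4 pil5, 2936 for growing, 1735 for the lines in the light and 31 growth-associated. Without the 3 arrays that stood apart the counts were 54 for Col dark 280 against 1240 min, 2 for the difference over time, 2045 for Col dark against light, 8 for the difference in the response to light, 32 for Col light over time and 25 growth-associated. Without 4 arrays they were 72, 11, 2240 and 8 in that order, 238 for the lines at dark 1240 min, 212 for pif4 pil5, 1367 for the lines in the light and 35 growth-associated. A fit of only the groups compared gave 0 for Col dark 280 against 1240 min (803 with limma unadjusted), 212 for Col dark against light, 2 for its difference from CCA1OX, 281 for the lines at dark 1240 min, 21 for pif4 pil5, 330 for the lines in the light and 0 for Col light over time (592 unadjusted). Without dim probe sets the difference in the response to light gave 4. The pif4 pil5 day comparison gave 18 without dim probe sets, 177 without the 3 arrays, 1485 from its own arrays and 1172 with a replicate block on these.

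With 1 array left out the counts ran from 1923 to 2841 for the lines over all times, 11 to 31 for Col dark 280 against 1240 min, 0 to 0 for CCA1OX over the same times, 0 to 4 for the difference over time, 471 to 1430 for Col dark against light, 1943 to 2721 for CCA1OX dark against light, 0 to 10 for their difference, 106 to 151 for the lines at dark 1240 min, 43 to 633 for pif4 pil5, 755 to 1823 for growing, 3 to 16 growth-associated, 373 to 1002 for the lines in the light, 4 to 24 for Col light over time and 0 to 96 for the pif4 pil5 days. Median centring and repeated quantile normalization moved no count by over 1.5 times. The signal of dim probe sets over background limits what arrays can show.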

Other observations

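The comparisons here, of light groups and of days, were all chosen only after the data were seen, 6 in number. In the light, where neither line was labelled growing, COR15B was higher in CCA1OX than in Col by 2.72 ± 0.49 (adjusted p = 9.77e-04) and COR15A by 2.81 ± 0.62 (adjusted p = 6.73e-03). The pectin methylesterase gene PME61 was higher by 1.77 ± 0.20 (adjusted p = 1.66e-07), and AT3G25150 fell by 2.57 ± 0.13 (adjusted p = 3.93e-19). In each of these genes 10 of 10 CCA1OX arrays lay beyond the Col mean. Of the Col arrays 10 of 10 lay beyond the CCA1OX mean, but 9 of 10 for COR15B, where Col light 1080 replicate 5 stood at 7.89. In all 375 probe sets were higher and 305 lower in CCA1OX. The count of 680 was 38 in the first campaign and 960 in the second, 914 with 45 arrays and 1193 with time course as a replicate block. It was 373 without Col light 1080 replicate 4, 418 without CCA1OX light 1080 replicate 2 and 437 without Col light 120 replicate 5.

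Within the light groups of Col, the 1080 min arrays were higher than the 120 min arrays for AT3G62550 (2.82 ± 0.44, adjusted p = 6.45e-04), CCL (2.29 ± 0.42, adjusted p = 7.97e-03) and the gibberellin receptor gene GID1A (0.59 ± 0.13, adjusted p = 3.85e-02), each in 5 of 5 arrays. In all 14 probe sets were higher and 1 lower. With limma the count was 0 in either campaign alone (950 and 630 at an unadjusted p under the threshold). It was 4 without Col light 1080 replicate 2, 8 without replicate 1 of that group, 7 without Col light 120 replicate 1 or 4 and 24 without replicate 3. The same comparison in CCA1OX gave 0 with limma (655 unadjusted), and the difference between the lines 0 (480 unadjusted).

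Among the 6 pif4 pil5 arrays, the 4 of days 5 and 6 were compared with the 2 of day 4 after GI had been seen to vary among these same arrays, so its change of -3.65 ± 0.70 restates what prompted the comparison and tests nothing. COR27 fell by 2.80 ± 0.65 (adjusted p = 4.70e-02) and XTH20 by 1.86, each in 4 of 4 later arrays, among 17 probe sets higher and 33 lower. With 1 pif4 pil5 array left out the count of 50 was 0 without replicate 1, 17 without replicate 2, 19 without replicate 3, 1 without replicate 4, 96 without replicate 5 and 17 without replicate 6. For Col and CCA1OX at the same minute the arrays that stood apart were left out. In Col, with 3 later arrays and 2 of day 4, 45 of the 50 moved in the same direction (68.6% of all probe sets) and 0 passed the threshold with limma, GI by -2.41 ± 0.71 (adjusted p = 0.183), where with all Col arrays it changed by -1.45. In CCA1OX 33 of the 50 moved in the same direction (56.4% of all probe sets), and COR27 moved the other way (1.62). A comparison of day 6 with day 5 within array batch 2 gave 0 with limma (1966 at an unadjusted p under the threshold).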
